A study of Mus musculus with 9 samples.

How the data were processed

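The material was colon content of Jup-floxed (WT) and inducible epithelial Jup-knockout (KO) mice, under basal conditions or after 2.5% DSS in drinking water for 5 days. Per the labels' protocols, genomic DNA was extracted with a fecal DNA kit, and 10 ng went into each library. Sequencing was paired-end on an Illumina MiniSeq with custom primers and a phage control library spiked in, per the labels. The amplified region, the read merging or denoising, the filters and any taxonomic assignment are not given in the sources used here. The design text gives n = 10 for the DSS experiment, and 9 samples are analysed here.

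The authors deposited a table of whole-number counts per feature and sample, not normalized, with 782 rows named by identifiers of 32 hexadecimal characters. The table does not pair these identifiers with sequences, taxa or genes. It holds 16 sample columns. The 9 columns whose names match a sample's description in the labels were used, and the other 7 were not used in any step. Of the rows, 106 had no count in the 9 samples. Groups and replicate numbers came from the sample titles. The table holds no host gene, so the genotype labels were not checked here.

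Tests were planned at the level of genera, with summed shares of phyla and of taxon lists. None of these could be made without names, so single features took the place of genera, and the lists have no result. Features were kept with 10 or more counts in at least 2 samples (491 of 676). The main test was edgeR 4.0.16 (R 4.3.3), with TMM factors, estimated dispersions and the quasi-likelihood F-test. One model with a mean for each of the 4 groups held all 9 samples, which share the estimate of the spread, and 7 contrasts were taken from it. P-values were adjusted within each contrast by Benjamini-Hochberg, and an adjusted p under 0.05 counts as past the threshold. The log2 differences are between group means on the model's log scale, averaged with equal weight over strata, so they can differ from ratios of mean shares. Standard errors are the log2 difference over the square root of F.

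Scaling matters in these samples. TMM factors ran from 0.561 in WT basal 1 to 2.17 in WT basal 2. The median log2 difference of all tested features between DSS and basal was 0.22 with TMM, −0.12 with library totals and 0.52 with DESeq2, which is small beside the differences called. Features taking over 10% of any sample numbered 6 and held 7.31% to 61.4% of a sample.

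Named features followed a rule fixed before the data were examined. For the pooled contrasts it took up to 12 past the threshold in each direction, then those of smallest p up to 20, then the 10 most abundant. For the other contrasts it took the 3 of smallest p where none passed. At most 2 identifiers that rose and 2 that fell are printed, those of largest log2 difference, and other features are named by rank of mean share. A feature with 0 counts in a group is given a bound from 3 counts per library, which is 0.000664% to 0.000879% of a library. Intervals of shares are 95% Wilson intervals. Floors and intervals cover counting error only, since PCR reads are not independent molecules. The floors also take it that low counts were not removed before the table was made, which is not known.

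Diversity was computed with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and figures with matplotlib 3.10.9. The Shannon index uses natural logs. Richness is the expected number of features at 341216 counts, the smallest total. Group differences were averaged over strata and tested two-sided against all 60 arrangements of the samples within the other factor. Permutational multivariate analysis of variance (PERMANOVA) used marginal terms and the same arrangements.

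The fits were tested on simulated counts for the DSS-against-basal comparison, drawn with the real means and totals for 491 features, 200 of them changed. With the dispersion set to 1, edgeR recovered 88.1% of 16-fold and 99.3% of 64-fold changes. The dispersions estimated from the samples were far higher, with a median of 5.18 (2.37 to 6.91). With these, edgeR recovered 0% of 4-fold, 0% of 16-fold, 0.917% of 64-fold and 41.8% of 256-fold changes. With no feature changed, edgeR made 0 calls in each of 5 runs and DESeq2 10 to 20, so the DESeq2 counts include false calls at this spread.

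No pair of samples in a group agreed within sampling noise (chi-square over its degrees of freedom 299 to 1350), so each was counted as 1 sample. Alternatives were DESeq2 1.42.0, limma 3.58.1 on centred log-ratios with a pseudocount of 0.5, library totals, no filter, a filter on 4 samples, the replicate number as a block, other indices and distances, and each sample left out in turn. DESeq2 gave no adjusted p to 149 of the tested features in DSS against basal; these stay out of counts of lost calls.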

Results

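DNA was sequenced from the colon content of mice with and without dextran sodium sulfate (DSS) colitis, in 2 genotypes. DSS damages the colonic epithelium and is a standard way to provoke acute colitis in mice. The knockout (KO) mice carried a floxed Jup gene and an inducible Cre recombinase under the villin promoter, which is active in intestinal epithelial cells; Jup encodes plakoglobin, a protein of desmosomes and adherens junctions. Mice with the floxed gene alone served as wild type (WT). DSS was given at 2.5% in the drinking water for 5 days. The 9 samples comprised 2 WT basal, 2 KO basal, 2 WT DSS and 3 KO DSS samples. The labels do not say whether each sample came from a separate animal, so p-values measure the spread between these samples, part of which may be technical. The sample titles name no cage or litter, so whether these coincide with treatment or genotype is not known. The deposited table gave counts per sequence feature, with no sequence or taxon beside the feature identifiers, so features are named here by their rank of mean share over the 9 samples. Total counts were 343292 and 341216 in WT basal, 404861 and 367750 in KO basal, 451515 and 362047 in WT DSS, and 361636, 407274 and 404927 in KO DSS. A sample held 241 to 361 features, and 84 of the 676 features seen in these samples were found in all 9.

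The 10 most abundant features of a sample held 55.1% to 77.8% of the counts of 7 samples, 36.4% of WT basal 2 and 43.0% of WT DSS 2, and which features these were differed from sample to sample. The feature of rank 1 averaged 16.7% ± 19.1 (SD, n = 4) of the counts in basal samples and 16.2% ± 8.98 (SD, n = 5) in DSS samples. Its share ranged from 43.3% in WT basal 1 to 1.89% in WT basal 2, the other sample of that group. In KO DSS samples the feature of rank 2 was uneven: it took 20.2% and 32.8% of KO DSS 1 and KO DSS 2, and 0.0528% of KO DSS 3. The feature of rank 3 took 32.4% and 11.2% of the WT DSS samples and at most 4.66% of any other sample. In DSS samples the feature of rank 4 averaged 7.65% ± 6.69 (SD, n = 5) against 0.513% ± 0.961 (SD, n = 4) in basal samples. It was at 1.95% in KO basal 2 and at most 0.0706% in the other 3 basal samples, and at 0.0852% in KO DSS 3 and 1.5% to 15.4% in the other 4 DSS samples. Its log2 difference of 5.44 ± 1.99 (SE) had an adjusted p of 0.13 with edgeR's quasi-likelihood test. The feature of rank 5 went the other way by value, with 6.44% ± 4.55 (SD, n = 4) in basal and 1.32% ± 2.26 (SD, n = 5) in DSS samples (edgeR adjusted p = 0.288). Among the DSS samples, KO DSS 3 held 5.34% and the others at most 0.549%. Of the 10 most abundant features, none passed the edgeR threshold between DSS and basal or between KO and WT samples. The 95% Wilson intervals of these single-sample shares reach at most 0.166 percentage points to either side, which covers counting error only.

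**Figure D1:**
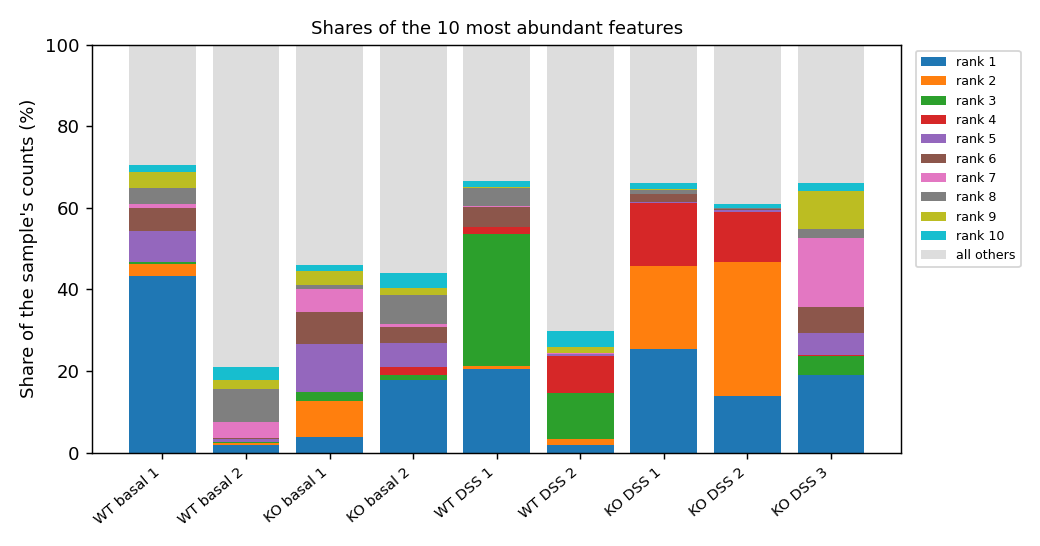
Shares of the 10 most abundant features in each of the 9 samples; the vertical axis is the percent of the sample's counts, each colour is a feature by rank of mean share, and grey is the sum of all others. The rank 1 feature takes 43.3% of WT basal 1 and 1.89% of WT basal 2, the rank 3 feature is highest in the WT DSS samples, and the rank 2 feature is highest in KO DSS 1 and KO DSS 2.

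The first comparison asked which features differ in acute colitis, averaged over both genotypes. Between the 5 DSS and 4 basal samples, 9 of 491 features tested passed a Benjamini-Hochberg adjusted p of 0.05 in edgeR's quasi-likelihood test, 7 higher and 2 lower with DSS. The most abundant of them, of rank 21, rose from 0.00373% ± 0.00443 (SD, n = 4) to 1.53% ± 1.08 (SD, n = 5), a log2 difference of 8.38 ± 2.28 (SE) with an edgeR adjusted p of 0.023. It held 1.33% to 2.94% of the counts of 4 DSS samples and was not detected in KO DSS 3. Its ratio of mean shares was 410, or 743 without WT basal 1. Feature 6ffed603109d2d169a33bdce03fa3c99, of rank 113, was detected in 5 of 5 DSS samples and in 0 of 4 basal samples, the only one of the 9 whose groups did not overlap. For a single feature, chance separates 5 samples from 4, in either direction, in 1.59% of splits. With all features searched, 20 of 60 relabellings within genotype gave 1 or more features found in all samples of one side and none of the other, in the same direction (exact permutation p = 0.333, one-sided). Its mean share was 0.165% ± 0.239 (SD, n = 5) with DSS, at least 199.7-fold higher than the basal samples allow (edgeR adjusted p = 0.023), or at least 81.2-fold without WT DSS 2. Feature 08b39cf76131fdc5f8d1f1f6be0c2feb, of rank 137, was found in 3 of 5 DSS samples and no basal sample and was at least 139.5-fold higher by mean share (edgeR adjusted p = 0.023), or at least 39.7-fold without KO DSS 1. These bounds set the DSS mean against 3 counts in each basal library, which is 0.000741% to 0.000879% of its counts. Values of 1 to 3 counts were rare, at 1 to 5 per sample, and how low counts were treated is not given. If low counts were removed before the table was made, this bound and all others given here as at least are too high.

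The features of rank 73 and 152 were also undetected in all 4 basal samples and were at least 437-fold and 116.6-fold higher with DSS. The first was found in 3 of 5 DSS samples, with 1.75% in WT DSS 2, and its bound was 18.2-fold without that sample. The second was found in 4 of 5. The features of rank 64 and 83 were each found in 3 of 5 DSS samples and 1 of 4 basal samples. They rose by 9.07 ± 2.52 and 8.83 ± 2.60 (SE) on the log2 scale, with 2.03% and 1.30% of the counts of KO DSS 2. Their mean shares were 68.7 and 73.2 times the basal ones, and 6.95 and 7.94 times without KO DSS 2. Without WT basal 2, the only basal sample with either, they were at least 546-fold and 350.6-fold higher. Feature bcaa663b6ba40455634757464f104af0, of rank 49, fell with DSS. It held 0.0287% to 3.17% of the counts of 3 basal samples and 3 counts in all in the DSS samples, a ratio of mean shares of 5490 (95% counting interval 1880 to 26600; log2 difference −11.64 ± 2.62 SE, edgeR adjusted p = 0.00452). That interval covers counting error only, and without KO basal 1, which held the 3.17%, the ratio was 199.6. Without KO DSS 3, which held the 3 counts, the basal mean was at least 1064-fold higher. Feature 539f049bd3eae43fe41be294bfa6b8b5, of rank 54, fell by 9.56 on the log2 scale (SE 2.38, edgeR adjusted p = 0.015). It held 0.0935% to 2.45% of 3 basal samples, was undetected in KO basal 2, and reached 0.0719% in KO DSS 3. Its ratio of mean shares was 51.3, or 12.4 without WT basal 1 and 2709 without KO DSS 3, which left 4 counts in the DSS samples. None of the 9 calls held in every fit that left out 1 sample: 0 features passed without WT basal 1, without KO basal 1 or without WT DSS 1, 1 without WT basal 2, 2 without KO basal 2, 3 without WT DSS 2, 5 without KO DSS 1, 4 without KO DSS 2, and 23 without KO DSS 3. DESeq2 called 41 features, limma on centred log-ratios 0, and library totals in place of TMM factors 5, of which 3 were higher and 2 lower. With 10 or more counts required in at least 4 samples, 0 of 300 features passed in edgeR, and with no filter 7 of 676 did.

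**Figure D2:**
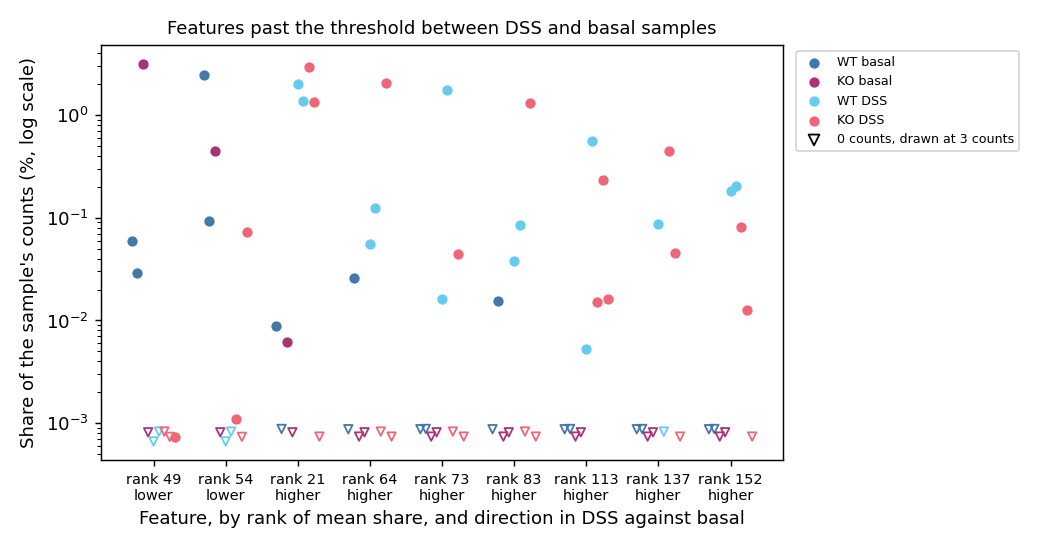
The 9 features past the edgeR threshold between DSS and basal samples, by rank of mean share; the vertical axis is the percent of each sample's counts on a log scale, filled points are samples coloured by group, and open triangles are samples with 0 counts, drawn at the share of 3 counts. The rank 113 feature is present in 5 of 5 DSS samples and in 0 of 4 basal samples, while the rank 21 feature reaches 1.33% to 2.94% in 4 DSS samples and is undetected in KO DSS 3.

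Taken by genotype, the comparison of DSS with basal samples had 2 basal samples on one side and 2 or 3 DSS samples on the other, with the spread shared over all 9 samples. In WT mice 0 features passed in edgeR, with 35 at an unadjusted p under 0.05. DESeq2 called 14 and limma 0. The smallest adjusted p was 0.0766, for the feature of rank 54, at 2.45% and 0.0935% in WT basal and undetected in WT DSS. The next were the features of rank 114 and 71, both detected in the 2 WT basal samples and in neither WT DSS sample (edgeR adjusted p = 0.204 for each). In KO mice 0 features passed in edgeR, with 31 at an unadjusted p under 0.05, while DESeq2 called 26 and limma 0. The smallest adjusted p was 0.06, for the feature of rank 49, at 3.17% in KO basal 1, undetected in KO basal 2, and at 3 counts in 1 of 3 KO DSS samples. The features of rank 64 and 83 followed (edgeR adjusted p = 0.179 and 0.253), each carried by KO DSS 2 alone among the KO samples. Without KO basal 2, 1 feature passed in KO mice. For the difference between the responses of the genotypes, the interaction, 0 features passed in edgeR, with 44 at an unadjusted p under 0.05. DESeq2 called 9 and limma 0 for it, and 1 feature passed in edgeR without KO DSS 1. The 3 features of smallest p were those of rank 54, 133 and 71, each with an adjusted p of 0.537.

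The comparison of genotypes asked whether loss of Jup from the intestinal epithelium goes with a different flora. Averaged over treatments, 0 of 491 features passed between the 5 KO and 4 WT samples in edgeR, with 50 at an unadjusted p under 0.05. Of the 60 relabellings within treatment, 13 gave at least 50 such features, the real one included. DESeq2 called 24 and limma 0. The feature of smallest p, of rank 35, held 0.997% ± 1.44 (SD, n = 4) of WT and 0.0205% ± 0.0215 (SD, n = 5) of KO samples (log2 difference −8.57 ± 2.40 SE, edgeR adjusted p = 0.175). It was detected in 3 of 4 WT and 3 of 5 KO samples, and WT DSS 2 with 3.09% carried most of the WT mean, the others lying at 0.798%, 0.0968% and 0. The feature of rank 104 lay at 0.0428% to 0.379% in the 4 WT samples and at most 0.0383% in the 5 KO samples, and that of rank 171 was found in 4 of 4 WT samples and 1 of 5 KO samples. Their edgeR adjusted p-values were 0.21 and 0.195. For the feature of rank 25 the means were 1.48% ± 2.00 (SD, n = 4) in WT and 0.0238% ± 0.0218 (SD, n = 5) in KO samples (edgeR adjusted p = 0.195). WT DSS 2 held 4.28%, WT basal 2 1.56% and the other WT samples at most 0.0837%. In the opposite direction, the feature of rank 182 was found in 3 of 5 KO samples and 0 of 4 WT samples, with a mean of 0.0703% ± 0.0814 (SD, n = 5) in KO (edgeR adjusted p = 0.195). The rank 2 feature averaged 12.4% ± 14.1 (SD, n = 5) in KO and 1.42% ± 1.15 (SD, n = 4) in WT samples (edgeR adjusted p = 0.751).

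Under basal conditions 0 features passed between the 2 KO and 2 WT samples in edgeR, with 15 at an unadjusted p under 0.05. DESeq2 called 8 and limma 0. The feature of smallest p, of rank 114, was at 0.794% and 0.0234% in the WT basal samples and undetected in the other 7 samples of the series (edgeR adjusted p = 0.453). In DSS colitis 0 features passed between the 3 KO and 2 WT samples in edgeR, with 39 at an unadjusted p under 0.05. DESeq2 called 9 and limma 0. The features of smallest p were those of rank 71, at 0.0556% and 0.702% in KO DSS 1 and KO DSS 3 and undetected in WT DSS, and of rank 67, at 1.89% in WT DSS 2, undetected in WT DSS 1, and at most 0.00148% in KO DSS samples. Their edgeR adjusted p-values were 0.489 and 0.55. At the spread seen here, simulated DSS-against-basal counts had 0% of 16-fold, 0.917% of 64-fold and 41.8% of 256-fold differences recovered by edgeR, while limma on centred log-ratios recovered 1.66%, 16.3% and 42.6%. Most differences of 64-fold or less would thus be missed by either in that comparison. DESeq2 recovered 27% of 16-fold and 54.3% of 64-fold differences there, but 22.6% and 19.3% of its calls were of unchanged features. Those shares belong to simulations with 200 of 491 features changed and cannot be carried over to the real calls. With no feature changed, DESeq2 still made 10 to 20 calls. In the real samples it called 41 features between DSS and basal, against a median of 27 over the other relabellings within genotype.

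Alpha diversity was compared with the Shannon index and with the number of features expected at the depth of the shallowest sample. The Shannon index was 3.61 ± 1.17 (SD, n = 2) in WT basal, 3.80 ± 0.108 (SD, n = 2) in KO basal, 3.60 ± 0.894 (SD, n = 2) in WT DSS and 3.06 ± 0.197 (SD, n = 3) in KO DSS samples. Averaged over genotypes, DSS minus basal was −0.37 (exact two-sided permutation p = 0.367 over 60 arrangements within genotype, of which the smallest possible is 0.0167). In KO mice each of the 3 DSS samples lay below both basal samples, a difference of −0.73. The exact permutation p was 0.1, the smallest that 3 against 2 samples can give here. In WT mice the difference was −0.0074, and the gap between these differences was not tested. KO minus WT, averaged over treatments, was −0.18 (exact permutation p = 0.733). The DSS difference turned to 0.0423 without WT basal 2, and the genotype difference turned to 0.236 without WT basal 2 and to 0.14 without WT DSS 2.

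Richness at equal depth was 299.5 ± 82.7 (SD, n = 2) in WT basal, 309.5 ± 9.23 (SD, n = 2) in KO basal, 342 ± 24.1 (SD, n = 2) in WT DSS and 316 ± 44.0 (SD, n = 3) in KO DSS samples. DSS minus basal was 24.3 features (exact permutation p = 0.5) and KO minus WT −8.2 features (exact permutation p = 0.833). The first turned to −4.93 without WT basal 1. The second turned to 21.1 without WT basal 2, 0.308 without WT DSS 2 and 2.46 without KO DSS 1.

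**Figure D3:**
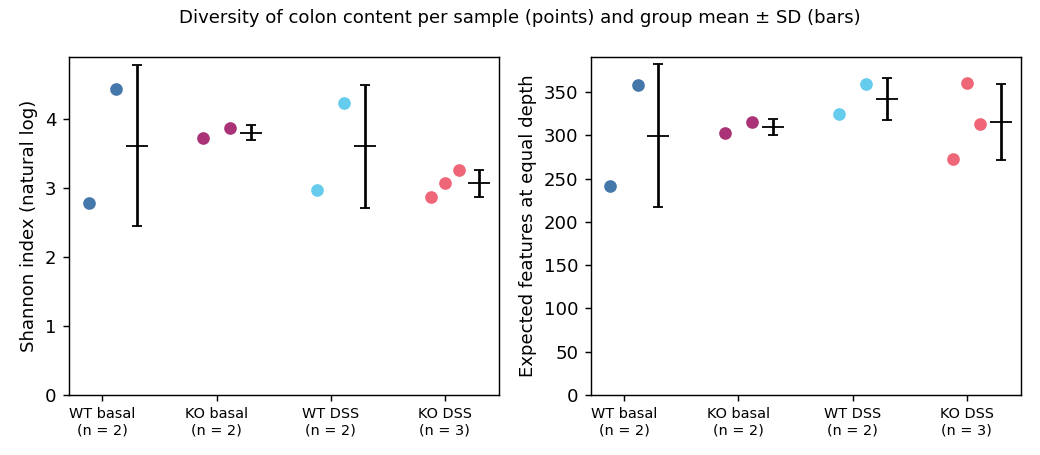
Shannon index (left) and expected number of features at the depth of the shallowest sample (right) by group; points are samples and the bars beside them are the mean ± SD. The 3 KO DSS samples lie at 2.86 to 3.26 on the Shannon index, below both KO basal samples at 3.72 and 3.87, while the WT samples of either treatment span 2.79 to 4.43.

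Whole communities were compared by Bray-Curtis distance, which is 0 for equal shares and 1 for no shared feature. The median distance was 0.648 over 6 pairs in the same group, 0.631 over 10 pairs that differed in treatment alone, 0.615 over 10 that differed in genotype alone and 0.715 over 10 that differed in both. The closest pair was KO DSS 1 and KO DSS 2 at 0.301. KO DSS 3 was nearest to WT basal 1, at 0.465, and its mean distance was 0.534 to the 4 basal samples and 0.673 to the other 4 DSS samples. Both WT DSS samples were also nearest to a basal sample, WT DSS 1 to KO basal 2 (0.533) and WT DSS 2 to WT basal 2 (0.537). Their mean distances were smaller to the other DSS samples (0.612 and 0.682) than to the basal ones (0.648 and 0.700). Treatment accounted for an R2 of 0.176 of the squared distances (permutational multivariate analysis of variance, pseudo-F 1.54, exact permutation p = 0.217) and genotype for 0.135 (pseudo-F 1.18, exact permutation p = 0.367). The genotype term reached an R2 of 0.224 without WT basal 1 (exact permutation p = 0.0333, over 30 arrangements).

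**Figure D4:**
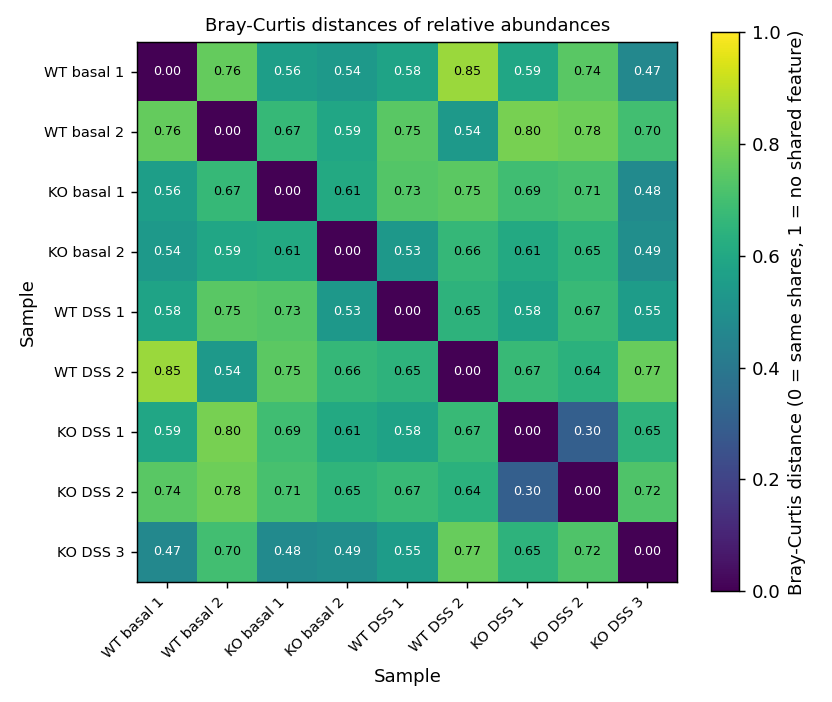
Bray-Curtis distances between all pairs of the 9 samples; rows and columns are samples and the colour and printed value give the distance, from 0 for equal shares to 1 for no shared feature. KO DSS 1 and KO DSS 2 are closest at 0.301, and KO DSS 3 is nearest to WT basal 1 at 0.465.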

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

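The alternatives were planned before the data were examined, except the sums of features with a near-constant ratio, the removal of features above 10% of any sample, the other detection limit and left-out samples for presence, and the left-out samples for ratios of mean shares, which were chosen after. The 9 calls between DSS and basal became 5 with library totals, all among the 9, 0 with limma on centred log-ratios, and 0 with 10 or more counts in at least 4 samples. No filter gave 7, the removal of abundant features 10, and summed sets 6. With the DESeq2 Wald test the counts were 41 for DSS against basal, 24 for KO against WT, 8 for KO against WT in basal mice, 9 in DSS mice, 14 for DSS in WT mice, 26 for DSS in KO mice and 9 for the interaction. DESeq2 shared 5 of the 9 calls and gave the other 4 no adjusted p, and it made 10 to 20 calls in simulated data with no change, so part of its excess is false calls. The cause of the other shifts was not tested. Leaving out a sample gave 0 to 23 calls for DSS against basal, 0 to 1 for DSS in KO mice and 0 to 1 for the interaction. The 23 calls without KO DSS 3 held all 9. Counts of the other contrasts stayed at 0 under library totals, limma, both filters and every left-out sample. Single-sample removal took the Shannon difference of DSS from −0.78 to 0.0423 and of genotype from −0.59 to 0.236, the richness difference of DSS from −4.93 to 53.6 and of genotype from −37.45 to 21.1, the treatment R2 from 0.16 (without KO DSS 2) to 0.258 (without KO DSS 3, exact permutation p = 0.0556), and the genotype R2 from 0.121 to 0.224. These differences stayed above an exact p of 0.05 throughout, but for that R2 of 0.224. Among single named features, 24 values passed the threshold with DESeq2 alone, 4 calls were lost with library totals, and none of the calls changed sign. With library totals, 2 features far from the threshold between DSS and basal did: rank 1 went from 0.159 to −0.0822 on the log2 scale and rank 10 from 0.0147 to −0.284.

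Samples with the same replicate number correlated at 0.0684 to 0.368 in their deviations over 6 pairs of groups, 4 of them over 0.1. Not every pair of groups passed 0.1 and the design gives no pairing, so the fits without a block stayed the main ones. Whether the numbers pair the samples stays open. With the replicate block the calls were 21 for DSS against basal (11 higher, 10 lower, including the 9), 1 for KO against WT, 1 in basal mice, 0 in DSS mice, 4 for DSS in WT mice, 4 in KO mice and 1 for the interaction. The treatment R2 with the replicate block was 0.233 (permutation p = 0.0333 over 60 arrangements that ignore the block, so no blocked test). The block also takes out KO DSS 3, the only sample numbered 3. Leaving out KO DSS 3 without a block gave 23 calls for DSS against basal. The treatment R2 was then 0.258 (exact permutation p = 0.0556, the smallest possible over 36 arrangements). For these results the block was not separated from leaving out KO DSS 3. Counts of the other contrasts stayed at 0 without KO DSS 3. The positive correlations are a hint from the data, not from the design. Alternatives that need taxon names (another taxonomic level, phyla and taxon lists, removal of other DNA sources) were not run. Totals of 341216 or more put the detection limit under 0.001%, if no low counts were removed before the table was made. The spread between samples, not depth, thus limits these results.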

Other observations

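The search for features of near-constant ratio, its summed sets, the comparison of presence, the check of library size and the comparison of held-out presence were chosen only after the results were seen.

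Many features rose and fell together at a nearly fixed ratio. Among 284 features with 10 or more counts wherever detected, in at least 3 samples, 91 of the 2876 pairs found in the same samples had an SD of the log2 count ratio of 0.25 or less. Shuffling each feature's shares among its samples gave a mean of 9.55 such pairs and at most 15 in 100 shuffles. The pairs joined 67 features into 20 sets. The largest held 8 features, of rank 182 to 333, found in KO basal 1, KO DSS 1 and KO DSS 2 and in no other sample. Of the 9 features called between DSS and basal, those of rank 64 and 83 form such a pair: in the 4 samples with either, their ratio was 1.45 to 1.66 and the SD of its log2 was 0.0926. As a hypothesis, the members of a set may be sequences carried by the same organism, such as copies of a marker gene that differ within a genome. Organisms that live together in a fixed ratio would give the same values and stay open, as the table holds no sequences. The 9 called features fall into 8 units when sets are merged. With each set summed, 444 units were tested and 6 passed, so calls were also lost apart from the merging.

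The calls between DSS and basal samples were weighed against chance, scaling and abundant features. Of the 60 relabellings within genotype, 2 gave at least the 9 features of the real labels, the real one included, and the highest other gave 14. By this count the share was under 0.05. By features at an unadjusted p under 0.05 it was not, as 4 of 60 gave at least the real 84. Nor was it by DESeq2, where 16 of 60 gave at least 41. As the outcome depends on the count used, chance is not excluded. The relabelling with 14 set WT DSS 1, WT DSS 2, KO DSS 1 and KO DSS 2 against the basal samples and KO DSS 3. With library totals the median log2 difference of the 9 features was 97.5% of that with TMM. Without the 6 features above 10% of any sample it was 99.4%. These medians could hardly have come out otherwise, so they are no test. TMM factors of 0.561 to 2.17, or features holding 7.31% to 61.4% of a sample, shift log2 differences by little beside the 8.38 or more called. The calls did depend on scaling, as 5 of the 9 were left with library totals. Without the 6 abundant features, 10 features passed. For KO against WT the count observed was 0, which all 60 relabellings reach by construction, so that count decides nothing there (highest other 3). By features at an unadjusted p under 0.05, 13 of 60 gave at least the real 50, the real one included (highest other 78). Chance is thus not excluded for genotype either.

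KO DSS 3 lay nearer to the basal samples (mean Bray-Curtis distance 0.534) than to the other DSS samples (0.673). Its total of 404927, within the range of the others, argues against a shallower library. If it were a basal sample under a DSS label, features called without it should not separate it from basal samples: of the 23 such features, it lay beyond all 4 basal samples at 4.35%, or 1 feature, against 20% of 5 for KO DSS 1, 50% of 4 for KO DSS 2 and 66.7% of 3 for WT DSS 2, each held out likewise. A feature called lower and undetected in a basal sample can never count, as no share lies below 0. Those of rank 49 and 54, undetected in KO basal 2, were the 2 lower calls without KO DSS 1 and without KO DSS 2. They were also among the 8 lower calls without KO DSS 3, so the percentages are not on equal terms. Among features called higher it was 1 of 3 for KO DSS 1, 2 of 2 for KO DSS 2, 2 of 3 for WT DSS 2 and at most 1 of 15 for KO DSS 3. With so few features, the measure can be low in another DSS sample. Of the features found in at least 3 of the other 4 DSS samples and no basal sample it held 1 of 26 (3.85%). On the features found in at least 3 of those 4 DSS samples and in none of 3 basal samples, KO DSS 3 and the fourth basal sample can be set side by side: it held 1 of 27 against 1 for WT basal 1, 4 of 40 against 14 for WT basal 2, 3 of 28 against 2 for KO basal 1 and 2 of 30 against 4 for KO basal 2. The other DSS samples, held out against the features found in all 3 that then remain, held 53.8% to 77.8% of 9 to 13 features. A wrong label may thus be a candidate explanation, but an animal that responded little to DSS gives the same values, and nothing here tells these apart, so the sample stayed in its group. The column names number the samples in sequence: the other 4 DSS samples, then the 4 basal samples, then KO DSS 3. Treatment thus follows that sequence except at KO DSS 3. What the numbers stand for is not given, so they do not decide the question.

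Presence of features also differed by value between DSS and basal samples. There were 33 features found in 3 or more DSS samples and no basal sample, against a median of 11.5 over the relabellings, and 5 in the reverse direction. As 3 of 60 relabellings gave at least 33 (highest other 37), chance is not excluded. At 10 or more counts the number was 40, and 2 of 60 relabellings gave as many, so the outcome depends on the detection limit. With 1 count as the limit it was 54 without WT basal 2, 15 without WT DSS 1, 12 without WT DSS 2, 20 without KO DSS 1, 14 without KO DSS 2, and 26 to 37 without any other sample. These 33 features held 0.114% of the counts in KO DSS 3 and 0.815% to 4.71% in the other DSS samples. It was also asked whether both genotypes shared a response: across 491 features, which are not independent replicates, their log-ratio differences between DSS and basal correlated at 0.258, and 6 of 60 relabellings gave as much, so the data do not decide.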
